A study of Sus scrofa with 6 samples.

How the data were processed

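Total RNA of 3 wild-type (WT) and 3 QQ pig embryos was made into TruSeq libraries and sequenced on an Illumina HiSeq 2000, per the labels' protocols. Extra-embryonic tissue of each embryo was genotyped, per the labels, which name 3 embryos per genotype and give no litter or dam, so p-values measure the spread between these 6 embryos only. Reads were placed on the pig genome Sscrofa10.2, per the submitters' processing notes; the aligner and the counting program are not given in the sources used here, nor is the use of strand. One table of the whole series was used. Per the file headers it holds, for each library and Ensembl transcript, the uniquely mapped read count, the percent of the transcript covered by reads, and the RPKM, with the transcript length. The deposited counts are whole numbers, and a dash stands for 0: with dashes read as 0, each library's counts add up to the total in its header. The deposited RPKM equals the count scaled to the transcript length and that total, with a relative gap of at most 1.29e-07. The authors' percent values were used only to compare how evenly transcripts were covered. All 20523 rows have at least 1 read in some library. Library totals ran from 12.2 to 13.5 in units of 1000000 reads, so 1 read in a 2000 bp transcript is worth 0.0371 to 0.0410 RPKM, and the floor of 3 reads lies at 0.222 to 0.246 CPM (counts per 1000000 reads). Intervals and floors cover counting error only.

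The test fixed before the data were examined was limma on log2(RPKM + 0.5), or edgeR if the table gave raw counts. It did, so edgeR 4.0.16 (R 4.3.3) was the main test, with TMM factors from 0.933 to 1.06, the default expression filter (minimum count 10, minimum total 15), quasi-likelihood fits without robust estimation, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter kept 13957 rows. The standard error of a log2 fold change is its size divided by the square root of the F statistic. VRTN fell below the filter and was kept in for its own test, with an exact two-sided permutation test beside it. Means and SDs are of the deposited RPKM over 3 embryos. No covariate was used.

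Rows carry transcript identifiers without gene symbols. A symbol was taken from the pig protein accession of the deposited best protein match (7171 rows), from the pig gene in the deposited KEGG match where 1 row alone had it (2252 rows), or from the deposited protein description (350 rows), through gene tables of Sscrofa11.1, whose positions served only to find genes within 1 Mb of VRTN. Accession and KEGG gene gave the same symbol in 98.9% of the 2780 rows that had both. In all 9773 rows had a symbol. Where a symbol had several rows (683 symbols), gene lists used the row with the most reads, and the values of a gene are those of that row; some rows are fragments of a gene. Of 665 genes in 26 lists fixed at the same time, 536 had a row. Each of the 25 lists with at least 5 tested members was tested with camera (limma 3.58.1) on the edgeR fit, with a preset correlation of 0.01 and adjustment over the lists, and again with an estimated correlation and with fry. Lists overlap, and some markers are expressed in several tissues.

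Named genes followed a rule fixed in advance: VRTN; the 10 largest fold changes in each direction with a symbol, an adjusted p under 0.05, a mean of at least 1 RPKM and groups that do not overlap, or, where fewer than 10 pass, up to 5 per direction with the smallest unadjusted p under the other conditions; the 2 tested members of each list with the smallest unadjusted p; and LFNG, HES7, DLL1, DLL3, MESP2 and TBX6 where measured. No gene passed, so the genes of the second part are named as not past the threshold; 1 of them is not reported here.

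Alternatives fixed in advance were no filter or a mean of at least 2 RPKM, median-ratio scaling, a threshold of 0.1, the replicate number as a block, leaving out each library, and limma on log2(RPKM + 0.5) with pseudocounts of 0.1 and 1, without a trend, with array weights, with median-ratio and with quantile normalization. DESeq2 1.42.0, robust estimation, and removal of each library's trend with transcript length (a loess curve with span 0.4, used as offsets) were chosen after seeing the data. The tests were checked on simulated counts of the 13957 rows with 200 changed genes: edgeR recovered 100% of genes changed 4-fold, 76.1% of those changed 2-fold and 13.4% of those changed 1.5-fold, with 9 false calls, and DESeq2 100%, 85.1% and 31.3%, with 26 false calls. The changed genes were drawn only from rows with many reads. Counts were drawn independently for each gene, without an outlying library. A HOX list shifted 1.25-fold in such counts had a camera adjusted p of 8.31e-09, and of 0.174 with an estimated correlation. No pair of libraries agreed within sampling noise: over pairs, the chi-square of the counts divided by its degrees of freedom was at least 7.54. Figures were drawn with matplotlib 3.10.9.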

Results

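The study asked which genes differ between whole pig embryos that carry 2 quantitative trait nucleotides of VRTN on both chromosomes (QQ) and wild-type embryos (WT), at the age when somites, the blocks of mesoderm that later form vertebrae, are being laid down. VRTN encodes vertnin, a protein tied to the number of thoracic vertebrae in pigs. Messenger RNA of Large White embryos at 17.5 to 18.0 days post coitum was sequenced, with 3 WT and 3 QQ libraries. Uniquely mapped reads, in units of 1000000 reads, were 12.5, 12.8 and 13.4 in WT replicates 1 to 3 and 13.5, 12.6 and 12.2 in QQ replicates 1 to 3. Of 20523 transcript rows, 13957 had enough reads to be tested. WT replicate 3 stood apart from the other libraries: on the first principal component, which held 57.7% of the variance, it lay at -61.7. WT replicates 1 and 2 lay at -9.13 and 1.00, and QQ replicates 1 to 3 at 10.9, 28.9 and 29.99, so this component also ordered the 2 groups.

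VRTN itself was almost silent in these libraries. Its transcript, of 3148 bp, had 2, 0 and 1 reads in QQ replicates 1 to 3 and 0 reads in each WT library. The 3 QQ reads, out of 38270376, came to 0.0784 CPM, counts per 1000000 reads (exact 95% Poisson interval 0.0162 to 0.229), and 0 of 38783463 WT reads allowed up to 0.0774 CPM. Both groups lay at or under the floor of 3 reads over the group, so no fold change was given, and a difference in VRTN was not detectable at this depth. The exact two-sided permutation test of log2(RPKM + 0.5) gave p = 0.4, where 0.1 is the smallest that 3 against 3 libraries allow, and the edgeR adjusted p was 0.311. The labels could therefore not be checked through VRTN.

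No single gene passed edgeR's quasi-likelihood test in either direction. The next genes were picked by the smallest unadjusted p among those with a symbol, a mean of at least 1 RPKM and separate groups. TRIM50, a ubiquitin ligase, had lower values in QQ embryos. Higher values were found for HELB, a DNA helicase, IER5, an immediate early response gene, and ELK4, an ETS transcription factor that works with serum response factor. TRIM50 stood at 3.12 ± 1.70 RPKM in WT and 0.411 ± 0.166 RPKM in QQ embryos (SD, n = 3 each), a log2 fold change of -2.99 ± 0.47 (SE). HELB stood at 1.16 ± 0.383 and 3.10 ± 0.665 RPKM in WT and QQ embryos, IER5 at 2.05 ± 0.659 and 6.32 ± 1.43 RPKM, and ELK4 at 1.32 ± 0.663 and 4.21 ± 0.627 RPKM, for log2 fold changes of 1.32 ± 0.27, 1.52 ± 0.31 and 1.59 ± 0.35. UBN2, a chromatin protein of the ubinuclein family, and a short row of PTPRF, a receptor tyrosine phosphatase, had log2 fold changes of 1.41 ± 0.30 and 0.91 ± 0.20. HELB, ELK4, UBN2 and PTPRF had their lowest read numbers in WT replicate 3 (34, 13, 58 and 140 reads). IER5 had its lowest in WT replicate 2 (17 reads). LOC100158115, annotated as acyl-coenzyme A thioesterase 4, RRP9, which binds the U3 small nucleolar RNA, and ABHD14A had log2 fold changes of -0.77 ± 0.16, -0.57 ± 0.13 and -0.72 ± 0.17. LOC100158115 belongs to a family of close copies among which reads can be split, so its value is uncertain.

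These 9 genes were taken from the 5 with the smallest unadjusted p in each direction under those conditions. That every QQ library lay on one side of every WT library was therefore a condition of the choice, not a result. The edgeR adjusted p of each was 0.233, which was also the smallest over all tested rows. Over all tested rows edgeR called 0 genes higher and 0 lower at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 2837 rows (1540 higher and 1297 lower in QQ), where chance gives about 698 on average. Genes varied together between libraries, so a single comparison can lie far from that average. Other splits of the 6 libraries into 3 and 3, each mixing WT and QQ, gave 85 to 1108 rows. In the real comparison the rows were 1407 higher and 1185 lower without WT replicate 1, and 2084 and 1568 without WT replicate 2. They were 1215 and 732 without WT replicate 3, and 1457 and 1470 without QQ replicate 1. Without QQ replicate 2 they were 788 and 432, and without QQ replicate 3 they were 712 and 383. With all 6 libraries and the length trend removed they were 1434 and 1440. The balance also moved with the scaling. Limma on log2(RPKM + 0.5), which used no TMM factors, gave 2046 higher and 646 lower at an unadjusted p under 0.05. At an adjusted p it called 0 in each direction. Limma gave 1588 and 1103 at an unadjusted p under 0.05 with median-ratio scaling, and 1363 and 1368 with quantile normalization. With array weights limma called 861 higher and 176 lower at an adjusted p of 0.05. The groups did not overlap in 29.6% of tested rows, against an average of 10% by chance for 3 against 3, which a single comparison can also miss widely. DESeq2 called 115 rows higher and 7 lower on the same counts, including all 9 genes named above (DESeq2 adjusted p between 0.000165 for TRIM50 and 0.0393 for RRP9), and the count moved with single libraries: it was 47 higher and 2 lower without WT replicate 1, 682 and 143 without WT replicate 2, 160 and 8 without WT replicate 3, 83 and 76 without QQ replicate 1, 3 and 1 without QQ replicate 2, and 0 and 0 without QQ replicate 3. The 9 genes were picked by their edgeR p on the same counts, so their DESeq2 calls are not independent support. In simulated counts of the 13957 rows for the same comparison, edgeR recovered 76.1% of genes changed 2-fold and 13.4% of those changed 1.5-fold, so small changes could be missed. DESeq2 made 26 false calls there and edgeR 9. DESeq2 recovered 21, 57 and 66 genes changed 1.5-, 2- and 4-fold, so its false share was above the threshold of 0.05. The simulated changes were placed only in rows with many reads, and the counts held no outlying library and no correlation between genes. The recovered shares can therefore be too high for the real counts, and larger changes in rows with few reads could be missed too.

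Most genes of the protein synthesis and respiration machinery had lower values in QQ embryos, a set-level call that camera made with a preset correlation and that did not hold with an estimated correlation (adjusted p = 0.882 for both sets). Of 62 tested ribosomal protein genes, 60 had lower values in QQ embryos, with a median log2 fold change of -0.33. All 38 tested genes of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, had lower values, with a median of -0.32. RPL9 stood at 635 ± 34.05 RPKM in WT and 534 ± 15.5 RPKM in QQ embryos (log2 fold change -0.35 ± 0.11), SDHC, a subunit of succinate dehydrogenase, at 78.3 ± 1.86 and 65.8 ± 3.99 RPKM (-0.35 ± 0.11), and NDUFB10, a complex I subunit, at 35.4 ± 4.90 and 28.2 ± 1.52 RPKM (-0.43 ± 0.14). RPL14 went the other way: its row, described as an L14-like protein, held 58, 74 and 79 reads in the WT libraries and 67, 822 and 720 in the QQ libraries, and without QQ replicate 1 it passed edgeR as higher (log2 fold change 3.38, adjusted p = 0.000708). RPL14 and RPL9 have near-identical copies, so their reads are uncertain. The list test camera called both sets lower, with an adjusted p of 1.02e-12 for ribosomal proteins and 1.92e-09 for oxidative phosphorylation. The exact two-sided permutation test of the library medians gave p = 0.1 for each list, the smallest that 3 against 3 libraries allow. Without WT replicate 3 both medians were -0.20. Under quantile normalization the median of the ribosomal list was -0.02 and its camera adjusted p 0.923, and the median of oxidative phosphorylation was -0.15. With limma and array weights the medians were -0.12 for each list. With limma and median-ratio scaling they were -0.31 for ribosomal proteins and -0.30 for oxidative phosphorylation. With all 6 libraries no single member passed edgeR, over all genes or adjusted over the list alone. WT replicate 3 was highest in both lists, with a list median 0.40 above the mean of the 6 libraries in log2, and the remaining libraries ranged from -0.28 to 0.07.

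Most HOX genes, which give segments along the body axis their identity, also had lower values in QQ embryos. Of 31 tested HOX genes 28 had lower values, with a median log2 fold change of -0.22 (camera adjusted p = 0.00700). The call did not hold with an estimated correlation (adjusted p = 0.882), and the exact two-sided permutation test of the library medians gave p = 0.2, where 0.1 is the smallest possible. With limma the median was -0.11 on log2(RPKM + 0.5), -0.084 with no filter and -0.11 with array weights. Those fits used no scaling between libraries beyond the read total. With limma the HOX median was -0.19 under median-ratio scaling and -0.27 under quantile normalization. HOXC6 stood at 38.5 ± 6.82 RPKM in WT and 27.96 ± 2.51 RPKM in QQ embryos (SD, n = 3 each), a log2 fold change of -0.56 ± 0.16, and HOXC4 at 27.7 ± 4.41 and 23.3 ± 0.524 RPKM, a log2 fold change of -0.35 ± 0.15. HOXA10 had a log2 fold change of -0.64 ± 0.29, HOXA5 of -0.29 ± 0.14 and HOXA11 of -0.28 ± 0.17. The 12 tested genes of paralog groups 5 to 9, expressed in the trunk, had a median of -0.22, and the 7 of groups 10 to 13, expressed further back, a median of -0.21. Neither smaller list passed camera (adjusted p = 0.163 and 0.336), but camera called the first lower without QQ replicate 2 (adjusted p = 0.0288) and the second lower without WT replicate 3 (adjusted p = 0.0195). With an estimated correlation neither of these held (adjusted p = 0.770 and 0.905). No HOX gene passed edgeR, over all genes or adjusted over the list alone.

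**Figure D1:**
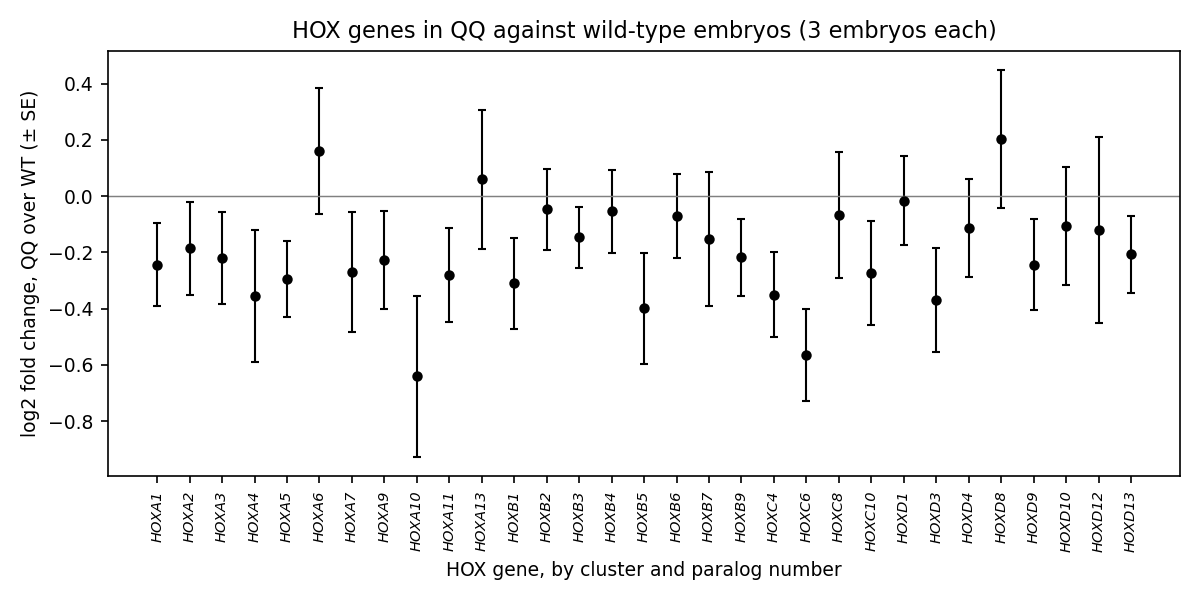
Log2 fold change of each tested HOX gene, QQ over WT, on the vertical axis, with bars of 1 standard error from edgeR, and the genes ordered by cluster and paralog number on the horizontal axis. Of the 31 genes 28 lie below 0, from -0.02 for HOXD1 to -0.64 for HOXA10, and none passed the test.

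The somite clock, the oscillating Notch, FGF and Wnt circuit that times the formation of somites, did not pass as a set. Of 29 tested genes of the clock and presomitic mesoderm, 21 had higher values in QQ embryos, with a median log2 fold change of 0.17 (camera adjusted p = 0.336). Without WT replicate 3 camera called the list higher (adjusted p = 0.0130), but not with an estimated correlation (adjusted p = 0.905). The median was 0.088 without WT replicate 1, 0.11 without QQ replicate 2, 0.078 with the stricter filter, 0.066 under quantile normalization and 0.32 with limma and array weights. LFNG, a glycosyltransferase that modulates Notch, stood at 22.1 ± 4.90 RPKM in WT and 23.95 ± 4.72 RPKM in QQ embryos, and the Notch ligand DLL1 at 11.5 ± 1.39 and 12.7 ± 3.10 RPKM, with log2 fold changes of 0.01 ± 0.19 and 0.04 ± 0.18 that turned negative in some of the alternative settings. The clock repressor HES7 and the ligand DLL3 had log2 fold changes of 0.42 ± 0.51 and 0.21 ± 0.28, which turned to -0.046 without QQ replicate 3 and to -0.073 without QQ replicate 2. MESP2 and TBX6 were not analysed here. ALDH1A2, which makes retinoic acid in the trunk mesoderm, had a log2 fold change of -0.33 ± 0.11, and SPRY2, a feedback inhibitor of FGF signalling, of 0.35 ± 0.15. In the Notch pathway 20 of 35 tested genes had higher and 15 lower values (camera adjusted p = 0.842). NOTCH2 stood at 18.2 ± 5.76 RPKM in WT and 29.8 ± 3.00 RPKM in QQ embryos (log2 fold change 0.62 ± 0.20), and HES4, a Notch target, at 4.99 ± 0.713 and 8.15 ± 1.53 RPKM (0.61 ± 0.20). NOTCH2 and HES4 had their lowest read numbers in WT replicate 3 (1338 and 70 reads). DESeq2 called a second, shorter NOTCH2 row higher (DESeq2 log2 fold change 1.33 ± 0.37, adjusted p = 0.0438), which had 36 reads in WT replicate 3 and 129 to 316 in the other libraries. None of these genes passed edgeR, over all genes or adjusted over either list alone.

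**Figure D2:**
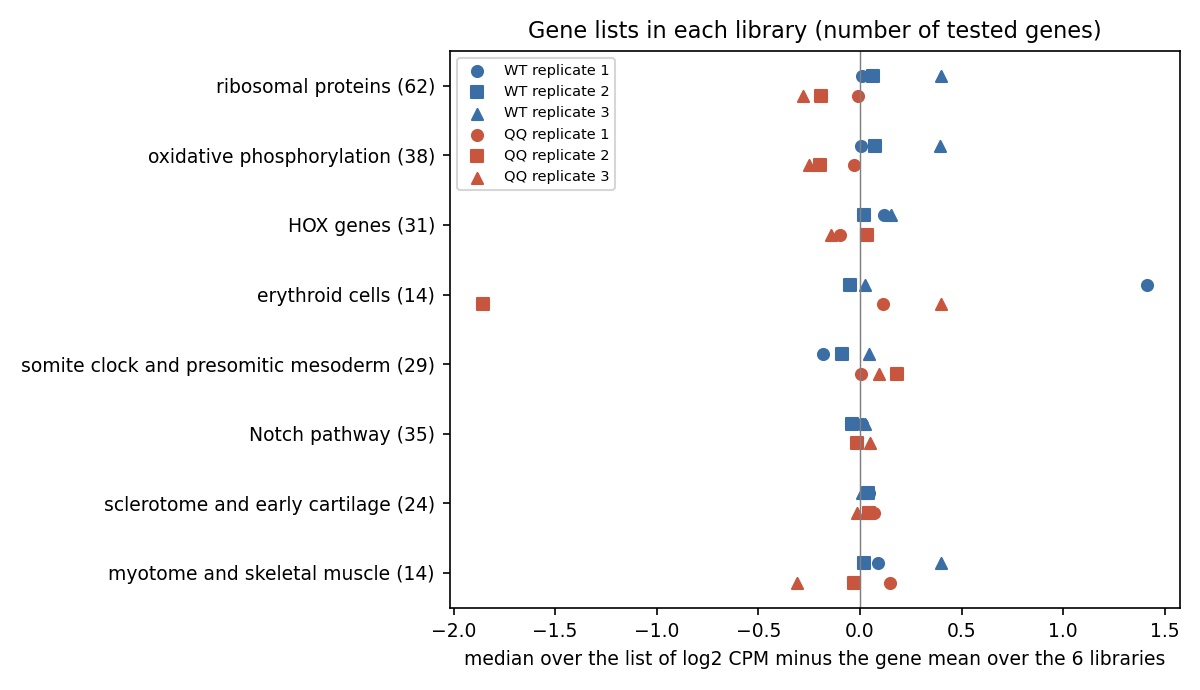
Median over the tested genes of 8 lists of the log2 CPM minus each gene's mean over the 6 libraries, on the horizontal axis, with 1 point per library, blue for WT and red for QQ embryos. The ribosomal and oxidative phosphorylation lists were highest in WT replicate 3, and the erythroid list ranged from -1.86 in QQ replicate 2 to 1.41 in WT replicate 1.

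Markers of the somite derivatives and neighbouring tissues gave no call at the level of lists. The 24 tested genes of the sclerotome and early cartilage, the source of the vertebrae, had a median log2 fold change of 0.07 (camera adjusted p = 0.979). Among them PTCH1, the hedgehog receptor, had a log2 fold change of 0.41 ± 0.14, and SCRG1, a cartilage-associated gene, of -0.59 ± 0.21. In the list of myotome and skeletal muscle 10 of 14 genes had lower values (median -0.20, camera adjusted p = 0.184), led by the intermediate filament gene DES (-0.44 ± 0.15) and the slow troponin TNNI1 (-0.44 ± 0.19); without QQ replicate 1 that list was called lower (adjusted p = 0.0108), but not with an estimated correlation (adjusted p = 0.800). The cardiac list was mixed (adjusted p = 0.842): MYL2, a ventricular myosin light chain, had a log2 fold change of -0.89 ± 0.26 and a TTN (titin) row of 1.76 ± 0.51, which DESeq2 called higher (adjusted p = 0.0361). The TTN row had 7 reads in WT replicate 3 and 26 to 130 in the other libraries. In the notochord and floor plate list the keratins KRT18 and KRT8, which epithelia also express, had log2 fold changes of -0.53 ± 0.15 and -0.36 ± 0.14, and that of KRT8 turned to 0.055 under quantile normalization. Neural tube markers (EGR2 0.59 ± 0.39, FABP7 -0.21 ± 0.20) and neural crest markers (ETS1 0.34 ± 0.21, EDNRB 0.28 ± 0.19) lay within 2 standard errors of 0. Camera gave adjusted p = 0.519 for the notochord, 0.960 for the neural tube and 0.842 for the neural crest list. No member of these 6 lists passed edgeR, over all genes or adjusted over its list alone.

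Blood and endoderm markers varied widely between single embryos of 1 genotype, with erythroid list medians from -0.05 to 1.41 over the WT and from -1.86 to 0.40 over the QQ libraries. All 14 tested erythroid genes had lower values in QQ embryos, with a median log2 fold change of -0.59, and camera called the list lower (adjusted p = 0.00905), but not with an estimated correlation (adjusted p = 0.882). The exact two-sided permutation test of the library medians gave p = 0.6, where 0.1 is the smallest possible. Without WT replicate 1 or without QQ replicate 2 the call ended (adjusted p = 0.492 and 0.277), with medians of -0.042 and -0.27. Leaving out WT replicate 2 or 3 gave medians of -0.99 and -1.01, and leaving out QQ replicate 1 or 3 gave -0.96 and -1.11. HBB, a beta-globin, had 28, 12 and 13 reads in the WT and 7, 0 and 11 reads in the QQ libraries, and GATA1, the erythroid transcription factor, had a log2 fold change of -1.09 ± 0.53. In the hepatic and yolk sac endoderm list (adjusted p = 0.842) APOB, the structural protein of lipoproteins, had 8, 6 and 4 reads in WT and 23, 15 and 285 in QQ libraries, and TDH had a log2 fold change of -0.27 ± 0.14; without QQ replicate 2 that list was called higher (adjusted p = 0.00394), but not with an estimated correlation (adjusted p = 0.796). Endothelial receptors KDR and TEK had log2 fold changes of 0.74 ± 0.33 and 0.78 ± 0.45 (list adjusted p = 0.798). Their rows held few reads, 14 to 51 per library for KDR and 3 to 16 for TEK. The median over the 12 tested endothelial genes was 0.04. For the trophoblast list, where camera pointed down and the median was 0.17, HSD17B1 had a log2 fold change of -0.51 ± 0.35 (list adjusted p = 0.942). PAG1 had 4, 12 and 12 reads in WT and 81, 2 and 7 in QQ libraries, and its log2 fold change of 1.59 ± 1.03 turned to -1.09 without QQ replicate 1. SAL1, a lipocalin of the endometrium list, stood at 7.50 ± 1.21 RPKM in WT and 2.86 ± 1.63 RPKM in QQ embryos, a log2 fold change of -1.46 ± 0.38. It passed edgeR when adjusted over the list alone (adjusted p = 0.0244) and DESeq2 over all genes (adjusted p = 0.0339), but not edgeR over all genes (adjusted p = 0.233). UPK1B, the next gene of that list, had a log2 fold change of -0.28 ± 0.19; camera gave the list an adjusted p of 0.336, and 0.00893 without QQ replicate 1 (adjusted p = 0.800 with an estimated correlation). No other member of these 5 lists passed edgeR, over all genes or adjusted over its list alone.

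Stress, glycolysis and cell cycle genes showed values on both sides. The heat shock gene HSPA1B stood at 505 ± 345 RPKM in WT, with 21125 reads in WT replicate 3, and 210 ± 37.4 RPKM in QQ embryos, and HSPH1 had a log2 fold change of 0.54 ± 0.19. HSPA1B has a near-identical copy, so its reads are uncertain. Camera gave the list of immediate early and heat shock genes an adjusted p of 0.739, and 0.00394 without QQ replicate 2 (adjusted p = 0.770 with an estimated correlation). GAPDH had a log2 fold change of -0.49 ± 0.18 and VEGFA of 0.39 ± 0.16 in the list of hypoxia and glycolysis (adjusted p = 0.339, and 0.00102 without QQ replicate 1, where the adjusted p was 0.800 with an estimated correlation). Of 25 cell cycle genes 17 had lower values (median -0.12, adjusted p = 0.374). CENPE, a kinetochore motor, had a log2 fold change of 0.69 ± 0.19, which DESeq2 called higher (adjusted p = 0.0496), and MCM3, a replication licensing factor, of -0.39 ± 0.12. CENPE had its lowest read number in WT replicate 3 (1387 reads). None of the genes in these 3 lists passed edgeR, over all genes or adjusted over its list alone.

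No gene or list of axial patterning signals passed edgeR or camera. In the list of TGF beta, BMP and GDF11 signalling 18 of 25 genes had higher values (median 0.09, camera adjusted p = 0.339). The inhibitor SMAD7 stood at 13.97 ± 2.48 RPKM in WT and 22.97 ± 4.96 RPKM in QQ embryos (log2 fold change 0.63 ± 0.18), and ACVR2B, a receptor for GDF11 that acts on vertebral identity, at 1.22 ± 0.726 and 3.08 ± 0.742 RPKM (2.38-fold in the edgeR fit). ACVR2B had 34, 49 and 12 reads in the WT and 61, 90 and 87 in the QQ libraries, so WT replicate 3 lowered its WT mean. In the FGF, Wnt and retinoic acid list (adjusted p = 0.842) the transcription factor SP8 had a log2 fold change of 0.64 ± 0.22. Among 18 other genes tied to vertebral number, 11 had higher values (median 0.17, adjusted p = 0.336), with ACVR2B and the histone acetyltransferase KAT6A (0.66 ± 0.24) closest to the threshold. Of 24 tested genes near VRTN, 12 had higher and 12 lower values (adjusted p = 0.842). ENTPD5, a nucleotide diphosphatase, stood at 4.04 ± 1.98 RPKM in WT and 9.93 ± 2.61 RPKM in QQ embryos (1.21 ± 0.35) and was called higher by DESeq2 (adjusted p = 0.0496), and TTLL5 had a log2 fold change of -0.64 ± 0.20. SP8, KAT6A and ENTPD5 also had their lowest read numbers in WT replicate 3 (56, 392 and 31 reads). SMAD7 had its lowest in WT replicate 1 (482 reads). In 4 lists the tested genes had a median and a mean log2 fold change of opposite sign, each with camera pointing down: cardiac muscle (-0.06 and 0.04), notochord and floor plate (0.03 and -0.10), FGF, Wnt and retinoic acid (0.00039 and -0.00038) and genes near VRTN (-0.015 and 0.018). None of the genes named in the signalling lists passed edgeR, over all genes or adjusted over its list alone.

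Long transcripts differed between libraries, most in WT replicate 3 but not in that library alone. In WT replicate 3 rows longer than 6000 bp had a median of -0.27 against the mean of the 6 libraries in log2 CPM. In QQ replicates 2 and 3 they lay on the other side, at 0.11 and 0.18. WT replicates 1 and 2 lay at 0.02 and -0.06, and QQ replicate 1 at 0.04. Between groups the median log2 fold change was 0.21 for the 691 rows longer than 6000 bp and -0.08 for the 2180 rows of 1000 to 1500 bp. The sex of the embryos was not analysed here, since no gene of the sex-linked list had a named row.

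**Figure D3:**
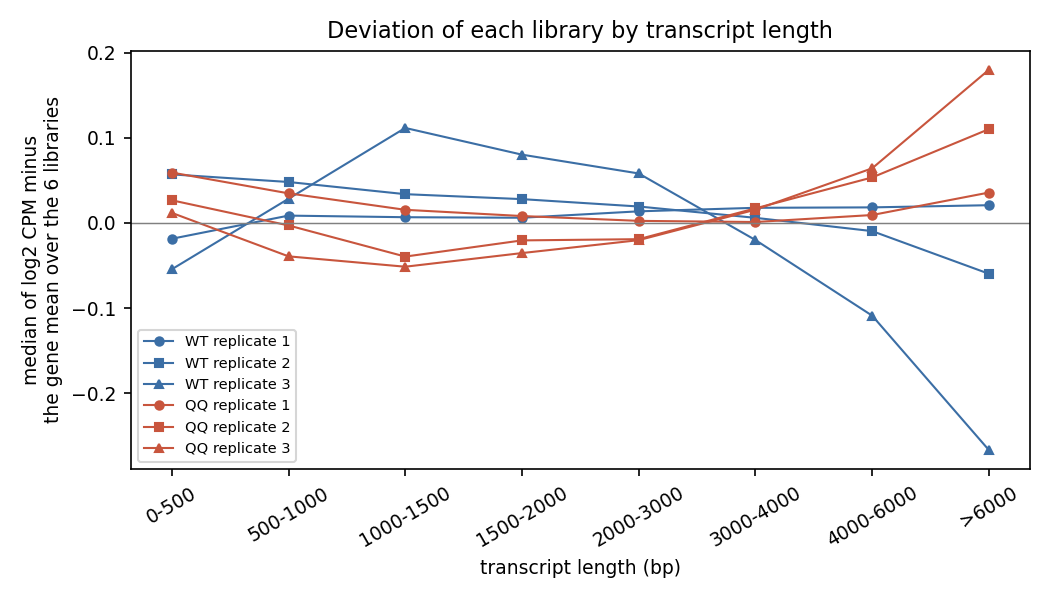
Median of log2 CPM minus each gene's mean over the 6 libraries, on the vertical axis, for tested rows in 8 classes of transcript length in bp on the horizontal axis, with 1 line per library, blue for WT and red for QQ embryos. For rows longer than 6000 bp WT replicate 3 lies at -0.27 and QQ replicate 3 at 0.18.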

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

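DESeq2, robust estimation, removal of the length trend, and that removal without WT replicate 3 were chosen after seeing the data. The edgeR counts of 0 higher and 0 lower stayed at 0 with no filter, the stricter filter, median-ratio scaling, a threshold of 0.1, robust estimation, the length trend removed, and limma in all forms except array weights, which called 861 higher and 176 lower. DESeq2 called 115 and 7. Without single libraries edgeR called 0 to 2 genes higher and 0 to 1 lower: a second RPL9 row without WT replicate 3 (log2 fold change 7.83), and RPL14 (3.38), an unnamed row (6.03) and ND2 (-1.21) without QQ replicate 1, named after their values were seen. The labels do not say whether the replicate numbers pair embryos. Correlations of same-number deviations were -0.19, 0.21 and -0.06, against -0.17 to 0.22 for other pairs of a WT and a QQ library, which cannot settle it. With the numbers as a block edgeR called 0 genes in each direction, with 1510 higher and 781 lower at an unadjusted p under 0.05. VRTN had p-values from 0.0702 to 0.871 over 24 alternatives (lowest adjusted p 0.308). None turned its direction, which says nothing on VRTN, since each WT library held 0 reads. Its depth of 3 reads is the limit. Leaving out 1 library gave 3 to 7 called lists (7 without WT replicate 3 with the length trend removed), and 0 were called with an estimated correlation, by fry for 1 direction or by fry for either direction. Camera with an estimated correlation also missed the shifted HOX list of the simulated counts, so it can miss a real shift. Over the alternatives the camera adjusted p, with these correlation settings included, ran from 5.65e-16 to 0.923 for ribosomal proteins, 1.35e-11 to 0.882 for oxidative phosphorylation, 0.000289 to 0.882 for HOX genes and 1.11e-07 to 0.882 for erythroid cells. Of 1428 recomputed gene values 1376 kept direction and side of the threshold, 41 came to pass it (26 with array weights, 14 with DESeq2) and 11 turned direction; of 625 list values 558 kept both, 11 came to pass, 11 ceased to pass and 45 turned direction. The sex alternatives were not run, since no sex-linked row was named.

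Without single libraries the log2 fold changes that turned ran from -0.13 to 0.23 for LFNG, -0.15 to 0.17 for DLL1, -0.073 to 0.36 for DLL3, -0.046 to 1.07 for HES7 and -1.09 to 2.14 for PAG1. The adjusted p of lists that turned ran from 0.631 to 0.965 for neural tube, 0.00394 to 0.794 for hepatic endoderm, 0.837 to 0.983 for sclerotome, 0.610 to 0.975 for cardiac muscle, 0.192 to 0.916 for trophoblast, 0.461 to 0.916 for FGF, Wnt and retinoic acid, 0.00394 to 0.983 for immediate early and heat shock, and 0.714 to 0.975 for genes near VRTN. Other lists that turned, with their adjusted p, were sclerotome (0.960), neural tube (0.925) and trophoblast (0.960) with no filter; neural tube (0.934) and trophoblast (0.996) with the stricter filter; sclerotome and neural tube with the block (0.998 each); and Notch (0.963), sclerotome (0.949) and trophoblast (0.963) with the length trend removed, where DLL1 stood at -0.0045. Without WT replicate 3 and with the length trend removed, sclerotome, cardiac muscle, trophoblast, and FGF, Wnt and retinoic acid turned (0.806 each). With limma, hepatic endoderm turned at 0.5 RPKM (0.817), pseudocounts of 0.1 (0.838) and 1 (0.836), no filter (0.656), the stricter filter (0.795), no trend (0.817) and array weights (0.817). FGF, Wnt and retinoic acid turned with no filter (0.912) and the stricter filter (0.951), and endothelium with median-ratio scaling (0.966) and the block (0.991). With quantile normalization KRT8 (0.055) and DLL1 (-0.052) turned, as did Notch, neural tube and notochord (0.989 each), cardiac muscle (0.923), endothelium (0.842) and cell cycle (0.755). The cause was not tested for any of these.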

Other observations

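The tests of WT replicate 3, of the abundance trend, of trunk tissue, of blood content, of the splits for genes higher and lower, and the DESeq2 calls were chosen only after the result was seen. Of the genes that DESeq2 called higher in QQ embryos, 4 are named here, chosen after their values were seen. NIPBL, which loads cohesin on chromosomes, stood at 18.3 ± 4.82 RPKM in WT and 32.4 ± 5.23 RPKM in QQ embryos (SD, n = 3 each; DESeq2 log2 fold change 0.74 ± 0.19, DESeq2 adjusted p = 0.0339). KMT2A, a histone H3 lysine methyltransferase that acts on HOX genes, had a DESeq2 log2 fold change of 0.84 ± 0.23 (adjusted p = 0.0413), and TET2, which oxidizes methylated cytosine, of 1.13 ± 0.30 (adjusted p = 0.0361). A row of APC, a negative regulator of Wnt signalling, had a DESeq2 log2 fold change of 1.06 ± 0.28 (adjusted p = 0.0339), and a second APC row an edgeR log2 fold change of 0.10 ± 0.13. None of these passed edgeR (adjusted p = 0.233), each had its lowest read number in WT replicate 3, and the rows that DESeq2 called higher had a median length of 2593 bp against 1974 bp for tested rows.

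Terms of the gene annotation in the deposited table, chosen after the data were examined, gave 23 called lower and 3 called higher of 524 tested by camera, and 0 with an estimated correlation (adjusted p = 0.884 for each term named here). The mitochondrial respiratory chain had a median log2 fold change of -0.31 (48 rows, adjusted p = 3.90e-09), the small ribosomal subunit of -0.33 (43 rows, adjusted p = 2.52e-08) and the small nuclear ribonucleoprotein complex, which splices RNA, of -0.32 (28 rows, adjusted p = 3.12e-05). Phosphatidylinositol metabolic process, with a median of 0.28, was called higher (28 rows, adjusted p = 0.0267). Of 23 tested genes within 1 Mb of VRTN, a window also set after the data were examined, LOC100158115 passed edgeR when adjusted over these genes alone (adjusted p = 0.0161), and DNAL1, an axonemal dynein light chain, had a log2 fold change of 0.92 ± 0.37. Hepatic and yolk sac endoderm genes spread from a list median of -1.13 in WT replicate 2 to 1.49 in QQ replicate 3 in log2.

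Ribosomal protein and oxidative phosphorylation genes had lower values in QQ embryos, by -0.32 in the library medians over the genes of both lists pooled. A trend with transcript length is argued against as the whole cause, since the difference was -0.31 ± 0.14 (SE) after its removal. Reads missing from parts of long transcripts in WT replicate 3 are argued against too, but only weakly. The median share covered of long rows was 77.5% ± 1.04 there and from 74.3% to 78.9% in the other libraries. The rows compared were chosen by each library's own read number, so they differed between libraries. Without WT replicate 3 the difference was -0.20 ± 0.08, and with the abundance trend removed it was -0.21 ± 0.11. Removing the abundance trend took the ribosomal list alone from -0.32 to -0.17 ± 0.10, and the oxidative phosphorylation list from -0.32 to -0.27 ± 0.13. WT replicate 3 and the abundance trend may each account for part of the difference, and both stay open. Genotype and the exact stage of the embryos stay open as well and were not tested.

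HOX genes had lower values in QQ embryos, by -0.17 in the library medians. A smaller share of trunk tissue in QQ embryos stays open: the sclerotome, somite and myotome lists together differed by 0.022 ± 0.067, and apart by 0.0015 ± 0.027, 0.17 ± 0.08 and -0.23 ± 0.18. The difference was -0.14 ± 0.07 without WT replicate 3 and -0.15 ± 0.07 with the length trend removed, whose errors keep both explanations open as part of the cause. A lower level of HOX transcripts with the QQ genotype, or a difference of stage within 17.5 to 18.0 days, may also be present and was not tested.

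Erythroid genes had lower values in QQ embryos, by -0.91 in the library medians, with WT replicate 1 highest and QQ replicate 2 lowest. Without these 2 libraries the difference was 0.27 ± 0.15, but they were picked as the extremes, which fixes that the difference shrinks, so this says nothing on its cause. The blood content of these 2 embryos and an effect of genotype on blood formation both stay open.

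The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. The real split called 0 genes higher and 0 lower by edgeR, and the highest of the others 0 and 0, so all 10 splits gave as many in each direction. At an unadjusted p under 0.05 the real split gave 2837 genes and the highest other 1108 (1 of 10 splits as large), and DESeq2 called 122 against 11 (1 of 10). For gene lists the real split called 4 and the highest other 10, and 9 of 10 splits called as many. The preset correlation of camera was 0.01, and the estimates were 0.778 for ribosomal proteins, 0.680 for oxidative phosphorylation, 0.096 for HOX genes and 0.929 for erythroid cells.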
